A study of Drosophila melanogaster with 29 samples.

How the data were processed

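Deposited tables were analysed for 3 kinds of RNA sequencing libraries from the adult Drosophila brain. The tables held 17713 measured features, of which 17612 were genes, 92 were spike-ins and 9 were transgenes. The bulk table held FPKM, fragments scaled to gene length and library size, a unit inferred from the deposited values because the file headers do not give it. The low-cell and single-cell tables held counts, which the authors deposited as whole numbers without normalization. Whether these counts are UMIs is not stated. The fold changes in the authors' own comparison tables were log2 values per the file headers, given as brain RNA over the sorted type, and the sign was turned here. The p-value and FDR columns of those tables were deposited by the authors from their own test, whose adjustment is not stated. The submitters named STARsolo and edgeR without versions, and the genome build and annotation are not stated. The symbols of 5 genes missing from the tables were taken from a reference table. The FPKM libraries have an unknown read depth, so depth could not be compared across the bulk libraries.

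Groups followed the labels: 4 bulk libraries of D7 neurons (2 from line SS02238 and 2 from line SS30295), 4 of EPG neurons (2 from SS00096 and 2 from SS00131), 2 of PEG neurons (SS02191), 2 of PEN2 neurons (SS02232) and 2 of whole brain RNA (WB). The low-cell groups were 14 PEN2 libraries (SS02232), 7 R4d libraries (SS00238) and 8 libraries of central brain RNA without the optic lobes (CB). The single-cell plates were 6 of PEN1 (SS62862) and 5 of PEN2 (SS02232). Where a label differed on the driver line (1 D7 library in the bulk table, 1 D7 title and 1 PEN2 plate table), the sample characteristics were followed. The low-cell libraries belong to 2 sample entries of PEN2, 1 of R4d and 1 of CB, and n counts libraries. The origin of the replicates, such as separate dissections, is not stated, so p-values measure the spread between these libraries.

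The low-cell and plate counts were compared with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest). The bulk FPKM were compared with limma 3.58.1, with a mean-variance trend, on log2(TMM-scaled FPKM + 1), because they are not counts. That scale understates the fold changes of genes with low FPKM. Bulk genes were kept with an FPKM of at least 1 in at least 2 libraries. Tested were 9500 bulk genes, 5553 low-cell genes and 6249 genes of the plates. All p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and a gene was called under an adjusted p of 0.05. All libraries of a protocol were fitted together with 1 term per cell type. Each sorted bulk type was compared with WB and with the equally weighted mean of the other 3 sorted types. The FPKM given for the other types are arithmetic means over all their libraries. The log2 changes come from log values with each type weighted equally, so they can differ from these means in size and sign. Low-cell PEN2 and R4d were compared with CB and with each other. Wells with at least 500 genes were summed per plate, after leaving out positions E12 to H12, and the plate was the sample. Software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

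The comparisons, tests, 30 gene lists and most alternatives were fixed before the data were examined. The form of the bulk test was conditional on the unit of the file. Gene lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists. Members that passed were also counted after adjustment over the list alone. Genes were named by a fixed rule. From each comparison the rule took the 6 largest changes per direction among genes called with a mean of at least 20 (FPKM, or CPM, which are counts scaled to the library size) in the higher group. Every bulk library of the higher group had to lie above every library of the lower group. In the count data, the group medians and 90% of the libraries had to lie on the group's side of the midpoint. From each list the rule took up to 3 called members and up to 1 other, and the transmitter release and pan-neuronal lists were taken in full. Genes named outside this rule are stated as such. Intervals and floors on fold changes cover counting error only. Where all libraries of a low-cell group held 0 counts, the fold change is given as a lower bound with a floor of 3 counts over the group.

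Alternatives were upper-quartile scaling, no scaling, no filter, an added threshold of 1 log2, a fit of only the groups compared, a replicate block, driver line terms, library sizes without the 261 ribosomal, mitochondrial and rRNA genes, DESeq2 for the count data, the well filter, the plate quadrant and leaving out each bulk library or plate. A lone library left by this was assumed to vary like the other groups. Added later were a pseudocount of 0.1 or 5, library weights, a ceiling of 10000 counts, reporter wells alone, the control positions kept, plates P394 to P396 left out and the settings of the concordance. DESeq2 was not run on the bulk data because they are not counts. No low-cell library was shallow, so leaving such libraries out changed nothing. A comparison against the control wells was planned only for column names that mark these wells, which they do not, and was not run. Counts at positions E12 to H12 showed the control pattern on 8 of the 11 plates. The plates without it, P394 to P396, were all PEN1 plates. Well percentages were compared by exact permutation over all splits of the 11 plates, also in wells thinned to 10000 counts.

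The tests of 8 of the 12 comparisons, without EPG and PEG, were tried on simulated data in which 200 genes were given a change of 1 or 2 log2. For changes of 2 log2, limma recovered 31.4% for D7 against WB, 8.3% for PEN2 against WB, 70.1% for D7 against the other types and 38.4% for PEN2 against the other types. edgeR recovered 53.9% for PEN2 against CB, 46.4% for R4d against CB, 54.5% for PEN2 against R4d and 46.6% for the plates. For changes of 1 log2 these were 2%, 0%, 14.6%, 1%, 20.6%, 16.5%, 15.5% and 7.2% in the same order. Calls at unchanged genes were 0% to 4.9% of the calls.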

Results

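RNA was sequenced from sorted neurons of the central complex of 3 to 5 day old flies and from whole or central brain RNA. The bulk libraries came from 754 to 1270 sorted cells each, and the 2 WB libraries from 5 ng of RNA. Between 4103 and 6106 genes reached 1 FPKM in a sorted bulk library, against 8597 and 8388 in WB. The reporter nls-tdTomato stood at 193 to 1525 FPKM in the sorted libraries and at 7.06 and 7.13 in WB. PEG replicate 1 differed from the other sorted libraries in its composition. In it, rRNA made up 41.9% of the FPKM and mitochondrial transcripts 34.0%, against 69.1% to 80.5% and 1.37% to 3.64% in the other 11. Between libraries of the same type, the correlation of log2 values was 0.72 to 0.8 in D7, 0.73 to 0.79 in EPG, 0.73 in PEG, 0.71 in PEN2 and 0.99 in WB. In PEG and PEN2 the replicates were no more alike than some libraries of different types. PEN2 replicate 1 correlated at 0.714 with PEG replicate 2 and at 0.707 with PEN2 replicate 2. PEG replicate 2 correlated at 0.739 with EPG SS00096 replicate 2 and at 0.733 with PEG replicate 1.

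The low-cell libraries held 399694 to 500622 counts from 35 PEN2 cells, 1001162 to 1154010 counts from 40 R4d cells and 340527 to 415414 counts from 50 pg of CB RNA. They detected 4725 to 5557 genes in PEN2, 6206 to 6478 in R4d and 7281 to 7519 in CB. The correlation between low-cell libraries of the same type was 0.58 to 0.64 in PEN2, 0.81 to 0.85 in R4d and 0.8 to 0.84 in CB. The reporter stood at 712 to 5190.3 CPM in PEN2, 6214 to 10000.5 CPM in R4d and 26.8 to 58.4 CPM in CB. The plates gave 380 wells of PEN1 and 362 wells of PEN2, and the counts summed per plate were 2444192 to 5783837. Of these wells, 241 of PEN1 and 106 of PEN2 held at least 10 reporter counts.

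The first question was which genes set D7 neurons apart from the EPG, PEG and PEN2 neurons, at n = 4 against 8 libraries. VGlut (FBgn0031424), the vesicular glutamate transporter, stood at 405 ± 50.7 FPKM (mean ± SD) in D7 and 10.7 ± 15.5 in the other types, 6.49 ± 0.99 log2 higher (± SE; adjusted p = 0.00228). The genes for acetylcholine release were all lower, VAChT (FBgn0270928) at 5.84 ± 6.46 against 122.5 ± 26.2 FPKM and ChAT (FBgn0000303) at 1.64 ± 2.81 against 36.6 ± 18.5. The largest rise was in the LIM homeobox gene Lmx1a (FBgn0052105), at 120.2 ± 34.1 FPKM in D7 and 0.0231 in the others (6.85 log2, adjusted p = 9.47e-07). The neuropeptide gene Proc rose by 6.13 log2 to 185 ± 57.2 FPKM, and the serotonin transporter SerT by 5.80 log2 to 65.8 ± 34.9. The homeobox gene hbn was at 19.7 ± 2.62 FPKM in D7 and listed at 0 in the other types.

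Single receptor, channel and adhesion genes also separated D7 from the other types. The tyramine receptor TyrR was at 25.4 ± 6.99 FPKM in D7 against 0.954 in the others, and the chloride channel gene pHCl-1 at 91.6 ± 18.5 against 21.7 ± 10.8. The gene mtt, a member of the glutamate receptor list whose ligand was not examined here, was at 47.7 ± 14.4 against 5.56. Lower in D7 were the neuropeptide precursor spab (3.15 ± 2.64 against 201 ± 32.5 FPKM), the homeobox gene Lim1 (0.680 against 75.5 ± 54.1), the adhesion gene dpr6 (0.834 against 73.5 ± 30.4) and the dopamine receptor Dop1R1 (3.53 against 139 ± 150.0). The GABA receptor Rdl was at 84.0 ± 39.9 FPKM in D7 and 303 ± 169 in the others (-1.46 log2, adjusted p = 0.0104). For Rdl the D7 libraries overlapped with those of the other types. EPG stood at 456 ± 53.6 FPKM, PEG at 147 ± 58.9 and PEN2 at 155 ± 39.1, so the mean of the others came mostly from EPG. Gad1 and VGAT, for GABA synthesis and release, did not pass (adjusted p = 0.376 and 0.328). The SD of the other types includes differences between these types.

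By gene list, all 3 genes for acetylcholine release were lower in D7 (3 adjusted over the list alone; camera adjusted p over the lists = 1.69e-06; adjusted p = 0.0463 with an estimated correlation). Of 22 beat and side adhesion genes, 1 was higher, 11 were lower and 10 did not pass (2 and 12 over the list alone; camera adjusted p = 8.55e-07), with beat-VII at 1.38 ± 1.60 against 19.7 ± 7.94 FPKM and beat-IIb at 0.123 against 19.1. Of 28 voltage-gated channel genes, 4 were lower and 24 did not pass (13 lower over the list alone; camera adjusted p = 2.92e-06), and most of these calls were lost without scaling. Of 7 GABA receptor genes, 3 were lower, among them Rdl and GABA-B-R3 (camera adjusted p = 0.00963, adjusted p = 0.0854 with an estimated correlation). Of 46 homeobox genes, 5 were higher and 5 lower. With limma, 444 of 9500 genes were called in D7 against the other types, 181 higher and 263 lower. Leaving out PEG replicate 2 raised this count to 661.

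**Figure D1:**
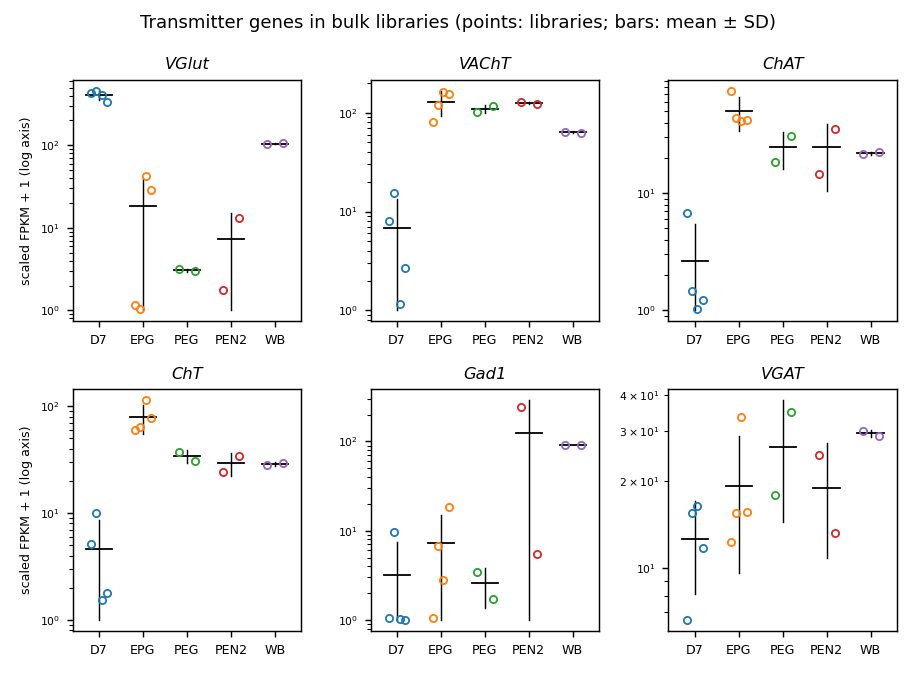
Genes for transmitter synthesis and release in the bulk libraries, with scaled FPKM + 1 on a log axis, 1 point per library and bars of the mean ± SD. VGlut stood at 334 to 453 FPKM in the 4 D7 libraries.

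The next comparison asked which genes set EPG neurons apart from D7, PEG and PEN2, at n = 4 against 8. The largest rises were in CG9896 (277 ± 134 against 3.09 FPKM, 6.61 log2), CG2016 (337 ± 176 against 32.1 ± 63.4, 6.49 log2) and CG14431 (93.3 ± 22.9 against 1.56, adjusted p = 6.82e-06). CG2016 varied widely among the other types, with PEG at 0.0188 FPKM. CR4575 (5.01 log2) and the transcription cofactor dac (FBgn0005677) followed, with dac at 37.5 ± 8.60 against 0.491 FPKM (4.72 log2). The muscarinic acetylcholine receptor mAChR-B stood at 87.1 ± 37.6 FPKM in EPG and 13.7 ± 11.7 in the other types, and the GABA receptor Rdl (FBgn0004244) at 456 ± 53.6 against 117.5 ± 51.9 (1.93 ± 0.28 log2, adjusted p = 0.00319). The potassium channel gene KCNQ was at 17.03 ± 8.53 FPKM against 0.503, and the calcium channel gene Ca-alpha1T at 197 ± 46.8 against 73.8 ± 95.1. Ca-alpha1T was no lower in PEN2, at 214 ± 101 FPKM, so it does not set EPG apart from PEN2. The dopamine receptor Dop1R2 rose by 2.63 log2 and the homeobox gene toy by 3.62 log2, to 132 ± 35.7 FPKM.

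Lower in EPG were the metabotropic receptor genes mGluR (1.42 ± 1.19 against 43.9 ± 29.3 FPKM) and mtt (0.0423 against 29.4 ± 22.7), the homeobox genes zfh2 (3.32 ± 1.80 against 81.4 ± 42.8, adjusted p = 3.36e-05) and ct (0.565 against 32.6), and the splicing factor mbl (12.2 ± 5.59 against 409 ± 220.0). Of these, ct was also low in D7, at 1.26 ± 1.06 FPKM. The innexin shakB, a gap junction subunit, fell from 23.1 ± 10.6 to 2.22 ± 2.32 FPKM, and the nicotinic subunit nAChRalpha6 from 76.5 ± 60.9 to 24.1 ± 5.01. ChAT stood at 49.5 ± 16.2 against 12.7 ± 13.5 FPKM (2.28 log2, adjusted p = 0.0279), and ChT, the choline transporter, at 77.8 ± 24.4 against 17.2 ± 15.2 (adjusted p = 0.0181). The ChAT call was lost without any 1 of SS00096 replicates 1 and 2, SS00131 replicates 1 and 2, PEG replicate 1 and PEN2 replicate 1 (adjusted p from 0.0524 to 0.1), without the filter and with a pseudocount of 0.1 (0.107). The ChT call was lost without SS00131 replicate 1 (0.0695) or 2 (0.057) and with a pseudocount of 0.1 (0.05). VAChT did not pass (128 ± 37.2 against 61.2 FPKM, adjusted p = 0.187). It stood at 109 ± 10.9 FPKM in PEG and 125 ± 3.81 in PEN2, and only D7 was low, at 5.84 ± 6.46.

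Of the 3 genes for acetylcholine release, 2 were higher in EPG (3 over the list alone; camera adjusted p = 0.000769, adjusted p = 0.236 with an estimated correlation). Of 22 beat and side genes, 6 were higher, such as side-II at 17.2 ± 5.68 against 1.42 FPKM, and 16 did not pass (8 higher and 2 lower over the list alone; camera adjusted p = 0.0388, adjusted p = 0.356 with an estimated correlation). Of 31 DIP and dpr genes, 4 were higher, among them dpr13 at 39.8 ± 8.51 against 3.31 FPKM, and 1 was lower (camera adjusted p = 0.374). Of 18 heat shock genes, 1 was higher although the list as a whole ranked lower (camera adjusted p = 0.00717, adjusted p = 0.269 with an estimated correlation). With limma, 244 genes were called in EPG against the other types, 122 in each direction. The count was 160 without EPG SS00131 replicate 1, 372 without PEN2 replicate 1 and 507 without PEG replicate 2.

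For PEG neurons the question was the same, against D7, EPG and PEN2, at n = 2 against 10. In both PEG libraries the octopamine receptor Octbeta2R (FBgn0038063) was raised, at 82.9 ± 20.4 against 6.51 ± 2.72 FPKM (3.69 ± 0.38 log2, adjusted p = 0.000533). The dopamine receptor Dop1R2 stood at 44.6 ± 4.74 FPKM against 13.9, the homeobox gene zfh2 at 138 ± 34.8 against 38.9 ± 35.9, and the neuropeptide gene CCHa1 at 12.97 ± 13.7 against 0.161. Dop1R2 was also high in EPG, at 33.6 ± 13.7 FPKM, and does not set PEG apart from EPG. Ca-alpha1T was lower, at 13.3 ± 6.80 against 135 ± 97.6 FPKM (-3.03 log2, adjusted p = 0.00126), as was CG42674 (-3.00 log2). ChAT did not pass (23.6 ± 8.49 against 25.2 FPKM, 0.90 log2, adjusted p = 0.681).

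Of the 6 largest rises in PEG, Gs2 and Eaat1 are on the glia list. Replicate 1, the library with 34.0% mitochondrial transcripts, held most of their FPKM. All 6 genes had an SD above their mean in PEG. The others were ogre, Msr-110 (441 FPKM in replicate 1 and 27.1 in replicate 2), CG31705 (231 ± 304 against 0.751) and CG13631 (104 ± 124 against 0.420). Gs2 (FBgn0001145), the glial glutamine synthetase, was at 3460 FPKM in replicate 1 and 134 in replicate 2, against 2.70 ± 4.88 in the other types. Eaat1, a glial glutamate transporter, was at 124 ± 157 FPKM against 0.125 and ogre, an innexin, at 126 ± 161 against 0.0462. Of 20 glia genes, 4 were higher and 16 did not pass (9 over the list alone; camera adjusted p = 1.33e-05, adjusted p = 0.426 with an estimated correlation). Without PEG replicate 1, 3 of these 4 were still called. Of 83 ribosomal protein genes, 2 were higher (4 over the list alone; camera adjusted p = 4.03e-10, adjusted p = 0.426 with an estimated correlation). None of 15 mitochondrial genome genes passed in limma, although the list ranked higher (camera adjusted p = 6.19e-05, adjusted p = 0.426 with an estimated correlation).

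Of 5 innexin genes, 1 was higher in PEG (3 over the list alone; camera adjusted p = 0.000217, adjusted p = 0.173 with an estimated correlation). This was ogre, at 240 FPKM in replicate 1 and 12.4 in replicate 2, against 0.0462 in the other types. Inx2, which did not pass, stood at 48.0 ± 66.4 FPKM. Both varied between the replicates as the glia genes did, so the list is not separate evidence from them. With limma, 182 genes were called in PEG against the other types, 144 higher and 38 lower. Without replicate 1 the count was 233, of which 94 were shared, and without replicate 2 it was 497, of which 125 were shared. With library weights it was 75.

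**Figure D2:**
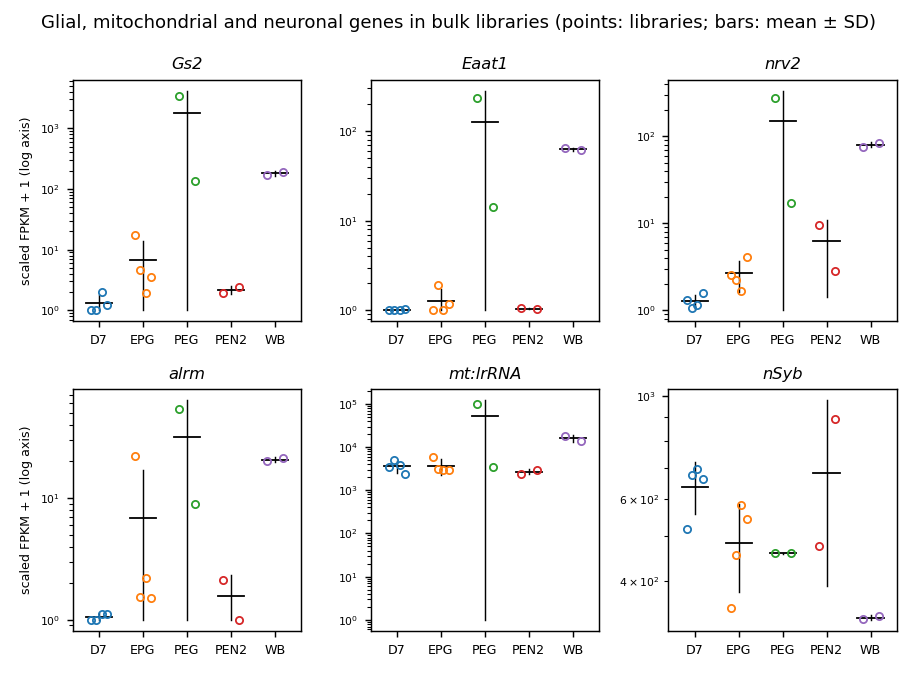
Glial, mitochondrial and neuronal genes in the bulk libraries, with scaled FPKM + 1 on a log axis, 1 point per library and bars of the mean ± SD. Gs2 was highest in PEG replicate 1, at 3460 FPKM.

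For PEN2 neurons, the comparison against D7, EPG and PEG had n = 2 against 10. The neuropeptide gene Dh44 (FBgn0012344) was at 201 ± 73.5 FPKM in PEN2 and 0.953 ± 1.63 in the other types (6.94 ± 0.75 log2, adjusted p = 0.000386). The diacylglycerol kinase gene rdgA (FBgn0261549) stood at 248 ± 159 against 2.89 FPKM, the transcription factor Ets65A at 67.7 ± 18.8 against 0.944, and the dopamine receptor Dop2R at 61.5 ± 18.5 against 10.4 ± 8.92. The homeobox gene Optix stood at 97.4 ± 6.86 FPKM against 3.55 (5.14 log2, adjusted p = 0.0103) and lost its call without replicate 2 (0.065), with a pseudocount of 0.1 (0.0531) and with library weights. The neuropeptide gene FMRFa was at 31.6 ± 32.7 against 0.602 FPKM (adjusted p = 0.0123, 0.0649 without replicate 1, and also lost with library weights). Lower were twz (0.499 against 76.2 FPKM, -4.69 log2) and the ribosomal protein gene RpL3 (0.944 ± 0.239 against 47.3 ± 18.5 FPKM, adjusted p = 6.43e-05). In the low-cell PEN2 libraries of the same line the mean of RpL3 was not below that of CB, with the values given under the other observations.

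Of 83 ribosomal protein genes, 4 were lower in PEN2, among them RpL3 and RpL37a (4 over the list alone; camera adjusted p = 4.86e-08, adjusted p = 0.465 with an estimated correlation). Of 31 DIP and dpr genes, 5 were higher and 26 did not pass (7 higher and 3 lower over the list alone; camera adjusted p = 0.00145, adjusted p = 0.166 with an estimated correlation). Of 6 pan-neuronal genes, 1 was higher (4 over the list alone; camera adjusted p = 0.000482, adjusted p = 0.0833 with an estimated correlation). Without scaling, the pan-neuronal call and most DIP and dpr calls were lost. With limma, 231 genes were called in PEN2 against the other types, 171 higher and 60 lower. With upper-quartile scaling, which moved the median by 0.2 log2, 346 genes were higher and 46 lower. The count was 454 without PEN2 replicate 1, 496 without PEG replicate 2, 144 without scaling and 61 with library weights.

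The comparisons of each sorted type with WB asked what separates a single neuron type from the whole brain. The titles of the WB libraries carry another number prefix than those of all sorted libraries. Its meaning is not stated, and a batch would not be separable from sorted against brain RNA in these comparisons, heat shock genes included. The rhodopsin gene Rh2 was listed at 0 in D7, PEG and PEN2 against 49.5 ± 2.05 FPKM in WB. ninaE, another rhodopsin gene, stood at 1.46 FPKM in D7 and 0.181 in EPG, against 91.0 ± 11.9 in WB. The neuropeptide gene ITP was at 0.0338 FPKM in D7 and listed at 0 in PEN2, against 36.9 ± 1.78 in WB. Of 20 glia genes, 14 were lower in D7, 14 in EPG, 6 in PEG and 12 in PEN2 (16, 17, 6 and 18 over the list alone; camera adjusted p = 1.39e-14, 6.68e-15, 5.34e-05 and 4.31e-11). With an estimated correlation, the glia list had adjusted p = 0.037 in D7, 0.0473 in EPG, 0.238 in PEG and 0.0588 in PEN2. Without PEG replicate 1, 11 glia genes were lower in PEG. Of 39 neuropeptide genes, 19, 21, 15 and 16 were lower in D7, EPG, PEG and PEN2 and 1 was higher in each. Of 46 homeobox genes, 24, 23, 16 and 17 were lower and 3, 0, 1 and 3 were higher in the same order. These comparisons share the WB libraries and are not compared with each other.

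Heat shock genes were higher in all 4 sorted types than in WB: 10 of 18 in D7, 9 in EPG, 11 in PEG and 9 in PEN2 (12, 10, 14 and 10 over the list alone). The camera adjusted p-values were 2.76e-13, 2.71e-11, 5.98e-16 and 7.15e-11, and fewer of these genes were called without scaling. Hsp70Bb was at 63.6 ± 11.3 FPKM in D7 against 1.15 in WB (4.89 log2, adjusted p = 4.93e-06), Hsp26 at 69.5 ± 20.4 against 1.21 in PEG, and Hsp70Bc at 53.2 ± 23.3 against 0.641 in PEN2. Other genes also stood above WB. In D7 these were Lmx1a (5.41 log2), bib (43.5 ± 8.33 against 0.473 FPKM) and SerT (65.8 ± 34.9 against 0.956). In EPG they were y (113 ± 38.1 against 1.56 FPKM), twz (158 ± 45.7 against 3.66) and tnc (49.8 ± 11.7 against 1.33), of which y was also called in D7 and PEG, twz in PEG and tnc in D7. VGlut was at 405 FPKM in D7 and 104 in WB without passing in limma (1.95 ± 1.37 log2, adjusted p = 0.575). Every D7 library, at 334 to 453 FPKM, lay above the WB libraries, at 102 and 106. The SE comes from the fit of all types together, and within EPG alone VGlut ranged from 0.03 to 41.2 FPKM. The missing call therefore does not show that D7 and WB hold equal levels of VGlut.

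Each of these comparisons rested on 2 WB libraries. With limma, 947 genes were called for D7 (186 higher), 886 for EPG (163 higher), 574 for PEG (108 higher) and 740 for PEN2 (181 higher). Without WB replicate 1 the counts were 47, 28, 14 and 17, and without WB replicate 2 they were 50, 30, 13 and 21. The calls given above for Lmx1a, bib, SerT, Hsp70Bb, Hsp26, Hsp70Bc, y, twz, tnc, Rh2, ninaE and ITP were kept in both. Without scaling, which moved the median by -0.84, -0.83, -0.85 and -0.92 log2, there were 1859, 1612, 1006 and 1459 calls, of which 62, 51, 37 and 36 were higher. With upper-quartile scaling PEN2 had 330 higher and 545 lower, and the median moved by 0.21 log2.

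In the low-cell libraries, PEN2 was compared with CB to describe the type at n = 14 against 8 libraries. These belong to 2 sample entries of PEN2 (8 and 6 libraries) and 1 of CB, so p-values measure the spread between libraries. ChAT stood at 2128 ± 409.9 CPM against 798 ± 109.8 in CB (1.41 ± 0.27 log2, adjusted p = 8.24e-05). Gad1 (FBgn0004516) stood at 8.47 ± 21.1 CPM against 478 ± 89.3 (-5.77 log2), VGAT at 45.6 ± 36.4 against 204 ± 28.2 and VGlut at 0.319 against 144 ± 58.8. VAChT and ChT did not pass (adjusted p = 0.0999 and 0.868). The neuropeptide gene FMRFa (FBgn0000715) was at 2736 ± 1156 CPM against 100.3 ± 19.6, and the transcription factors Optix (FBgn0025360) at 1097 ± 216 against 37.5 ± 23.9 and run at 553 ± 245 against 15.4. The nicotinic subunit nAChRalpha6 (FBgn0032151) rose by 1.93 ± 0.14 log2 to 3260 CPM, the dopamine receptor Dop1R1 by 2.37 log2 to 437 ± 178 and Rdl by 0.59 ± 0.08 log2 to 4579 ± 685.

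Ca-alpha1T stood at 689 ± 187 CPM against 82.8 ± 18.7 in CB, and the active zone genes Rim at 2439 ± 353 against 542 ± 55.7 and brp at 515 against 204. The SNARE regulator cpx was lower, at 949.7 against 4292 CPM. Of 18 genes of the synaptic machinery, 4 were higher and 8 lower (4 and 9 over the list alone; camera adjusted p = 0.611). Of 23 voltage-gated channel genes, 10 were higher, 2 lower and 11 did not pass (12 and 2 over the list alone; camera adjusted p = 2.55e-05). Of 7 activity-regulated genes, 4 were higher (4 over the list alone; camera adjusted p = 0.000587), including Hr38 at 904 ± 501 against 247 CPM. Of 6 pan-neuronal genes, 4 were higher, such as elav (5 over the list alone; camera adjusted p = 0.000376). Of 82 ribosomal protein genes, 25 were higher and 10 lower (26 and 13 over the list alone; camera adjusted p = 8.92e-05, adjusted p = 0.281 with an estimated correlation).

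Most genes of the glia, neuropeptide and mitochondrial lists were lower in PEN2. Of 13 glia genes, 12 were lower (13 over the list alone; camera adjusted p = 1.13e-18), with the astrocyte gene alrm at 0.304 against 539 CPM. Of 30 neuropeptide genes, 3 were higher and 24 lower (the same over the list alone; camera adjusted p = 1.46e-19), with Ms at 0.470 against 2256 CPM and Pdf, without a count in PEN2, at least 745-fold lower. Of 13 mitochondrial genes, 11 were lower (12 over the list alone; camera adjusted p = 3.24e-10), with mt:ATPase6 at 1513 ± 463 against 11748 CPM. All 3 genes on the list for GABA release, Gad1, VGAT and the GABA transporter Gat, were lower (camera adjusted p = 2.29e-05). Gat need not mark the transmitter of a neuron, as it was raised together with glia genes in bulk PEG. Lower as well were 5 of 7 genes for monoamine release (camera adjusted p = 4.6e-05), with the monoamine transporter Vmat at 0.280 against 1070 CPM. Ddc, for dopamine and serotonin synthesis, did not pass (adjusted p = 0.182). Of 4 innexins, 3 were lower (camera adjusted p = 0.00268). With edgeR, 1009 of 5553 genes were called in PEN2 against CB, of which 614 were lower. Without the filter on low counts there were 2377.

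The comparison of R4d ring neurons with CB had n = 7 against 8 libraries, each group from 1 sample entry. Of the 3 genes for GABA release, Gad1 (662 ± 46.1 CPM against 478 ± 89.3 in CB, adjusted p = 0.653) and VGAT (143 ± 32.2 against 204 ± 28.2, adjusted p = 0.6) did not pass. The third on this list, Gat, a GABA transporter, held no count in R4d, at least 1390.0-fold lower (camera adjusted p of the list = 0.094). Gat need not mark the transmitter of a neuron. In bulk PEG it was raised together with the glia genes Gs2 and Eaat1, at 122 ± 148 against 1.95 FPKM. ChAT stood at 15.97 ± 13.3 against 798 ± 109.8 (-5.63 log2, adjusted p = 2.43e-14), VAChT at 1.32 against 94.8 CPM, and VGlut held no count in R4d, at least 358-fold lower. Rdl rose by 2.28 ± 0.10 log2 to 14776 ± 906 CPM (adjusted p = 6.27e-20), brp by 2.72 ± 0.22 log2 to 1348 ± 333 and nAChRalpha6 by 2.40 ± 0.16 log2 to 4504 ± 741. The highest gene count was 12471 to 17907 in all low-cell libraries whatever their depth, as a ceiling on counts would give. Rdl exceeded 10000 counts in some library, so its fold changes may be understated. The gene CG14342 was at 213 ± 23.6 CPM in R4d without a count in CB, at least 222-fold higher. The replication gene Mcm5 was at 203 CPM against 1.10. Snap25, a SNARE gene, stood at 319.6 against 2640 CPM and Ddc at 131 against 1319.

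Ribosomal protein genes rose as a group in R4d, 75 of 82 being higher (77 over the list alone; camera adjusted p = 8.66e-33), with RpLP1 at 2438 ± 358 against 509 CPM and RpS20 at 1436 against 254. Most adhesion genes were lower: 23 of 28 DIP and dpr genes with 1 higher (camera adjusted p = 5.87e-09), and 17 of 21 beat and side genes (camera adjusted p = 2.4e-09). Of 9 glutamate receptor genes 6 were lower (camera adjusted p = 0.000124), and all 4 innexins were lower (camera adjusted p = 0.00155). Of 30 neuropeptide genes, 1 was higher and 26 lower (camera adjusted p = 4.99e-24), and all 13 glia genes were lower (camera adjusted p = 4.27e-14). Of 18 genes of the synaptic machinery, 2 were higher and 10 lower (camera adjusted p = 0.0272). With edgeR, 1517 genes were called in R4d against CB, 598 higher and 919 lower. The count was 2850 without the filter on low counts and 2493 with only these 2 groups in the fit. The R4d libraries held 1001162 to 1154010 counts, more than those of CB.

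PEN2 and R4d were then compared directly, without the brain RNA, at n = 14 against 7 libraries from 2 and 1 sample entries. ChAT was 7.05 ± 0.39 log2 higher in PEN2 (2128 ± 409.9 against 15.97 ± 13.3 CPM, adjusted p = 1.37e-16) and Gad1 -6.24 ± 0.62 log2 (8.47 against 662 ± 46.1, adjusted p = 3.52e-10). PEN2 alone held counts of FMRFa (at least 6828-fold higher), Optix (at least 2736-fold) and ct (at least 2351-fold), and Dh44 stood at 2383 ± 696 CPM against 0.132. R4d alone held counts of the transcription factors D (FBgn0000411; 1189 ± 197 CPM, at least 2512-fold higher than in PEN2), Poxn (738 ± 184 CPM) and ara (460.4 CPM). The gene CG14687 (FBgn0037835) was at 7615 ± 483 CPM in R4d and 0.483 in PEN2 (-13.47 log2, adjusted p = 7.31e-31).

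Synaptic and receptor genes differed in both directions. Rim stood at 2439 ± 353 CPM in PEN2 against 253 in R4d, while Rdl (-1.69 ± 0.08 log2) and brp (-1.39 log2) were lower in PEN2. Of 9 glutamate receptor genes, 6 were higher in PEN2 (camera adjusted p = 7.79e-06), with Neto, an auxiliary subunit, at 340.4 ± 142 against 0.709 CPM. Of 28 DIP and dpr genes, 21 were higher and 2 lower (23 and 2 over the list alone; camera adjusted p = 9.27e-12), with dpr8 at 449 ± 105 against 2.95 CPM. Of 21 beat and side genes, 15 were higher (16 over the list alone; camera adjusted p = 9.97e-13). Of 7 activity-regulated genes, 5 were higher (camera adjusted p = 2e-05), with Hr38 at 904 ± 501 against 70.5 CPM. Of 18 homeobox genes, 11 were higher and 4 lower (camera adjusted p = 0.00202), and of 82 ribosomal protein genes 72 were lower (77 over the list alone; camera adjusted p = 4.35e-26). With edgeR, 1300 genes were called in PEN2 against R4d, 653 higher and 647 lower. Without the filter on low counts there were 2226.

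**Figure D3:**
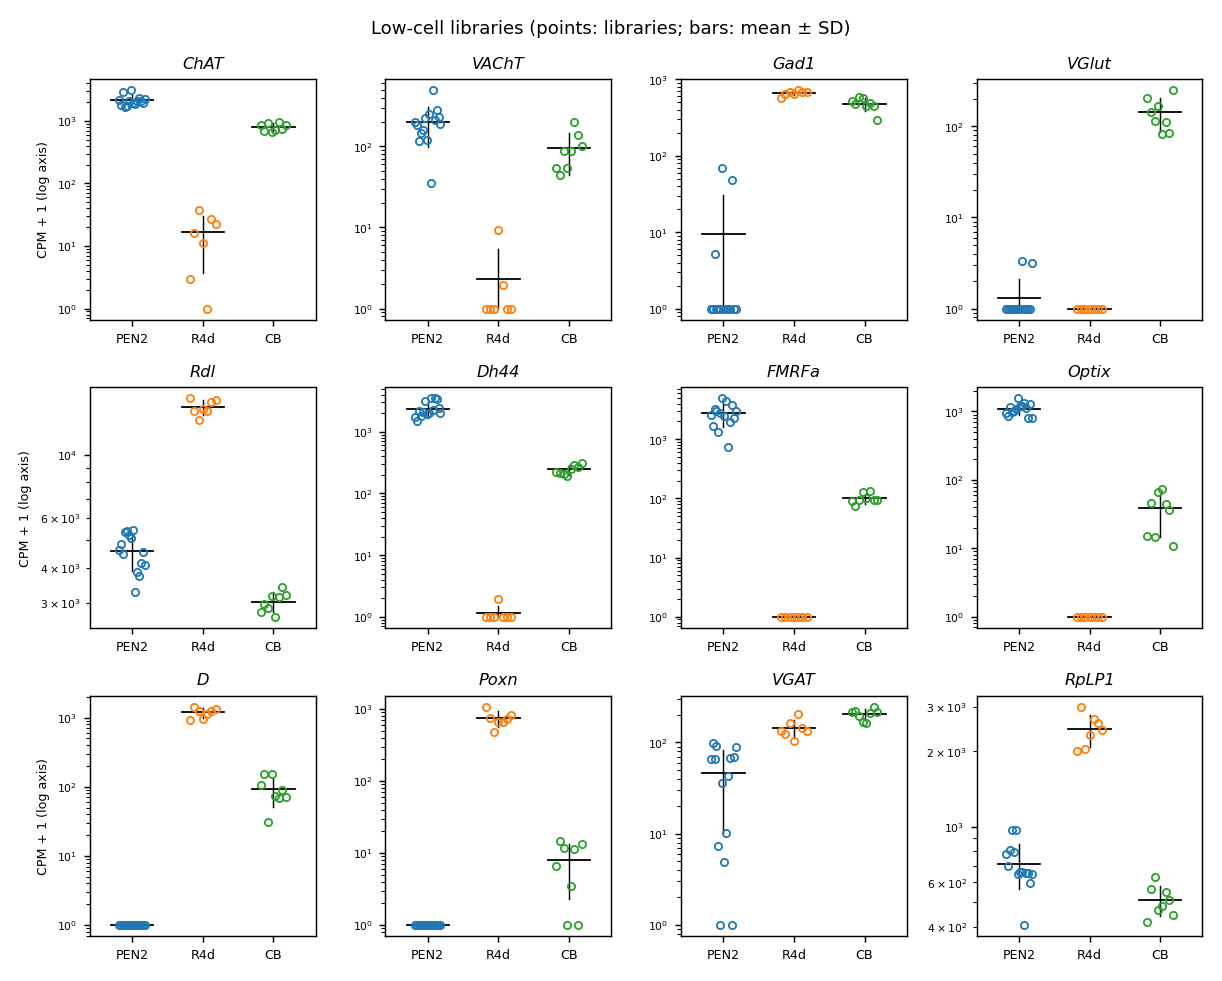
Genes of the low-cell libraries of PEN2, R4d and CB, with CPM + 1 on a log axis, 1 point per library and bars of the mean ± SD. ChAT was at 2128 CPM in PEN2 on average, 15.97 in R4d and 798 in CB.

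The plates asked how PEN1 differs from PEN2, at n = 6 against 5. Each type came from a single driver line, so type and line cannot be told apart. Plates P394 to P396, which lacked the control pattern, were all PEN1 plates. CG43658 (FBgn0263706) was at 735 ± 159.8 CPM in PEN1 and 103 ± 43.8 in PEN2 (2.84 ± 0.28 log2, adjusted p = 1.16e-05). Higher in PEN2 were the transcription factor br (FBgn0283451; 46.0 ± 44.8 in PEN1 against 659 ± 292 CPM, -3.84 log2, adjusted p = 0.00312), CG30419 (52.0 ± 19.6 against 343 ± 105, adjusted p = 0.000435), the transcription factor zld (17.6 ± 10.4 against 201 ± 62.9) and the adhesion gene dpr3 (73.0 ± 38.1 against 357 ± 89.0). In the low-cell PEN2 libraries br was at 788 ± 359 CPM, dpr3 at 386.5 ± 236 and CG30419 at 279.6 ± 171. There zld was at 81.5 ± 85.4 CPM, below the PEN2 plates, and rdgA at 1527 ± 393.6, nearer to the mean of the PEN1 plates. The zld call was lost with the control positions kept, and the dpr3 call with plates P394 to P396 left out. rdgA was 0.94 ± 0.16 log2 higher in PEN1 (1874 ± 197 against 979.97 CPM, adjusted p = 0.00718), a call lost without plate P388 or without plates P394 to P396.

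Between the plate sums of PEN1 and PEN2, ChAT (2855 ± 493 against 2031 ± 466 CPM, adjusted p = 0.537) and Gad1 (39.3 ± 46.6 against 224 ± 214, adjusted p = 0.405) did not pass. FMRFa and Rdl had an adjusted p of 0.999. None of 82 ribosomal protein genes passed in edgeR, although the list ranked lower in PEN1 (camera adjusted p = 0.00161, adjusted p = 0.823 with an estimated correlation). Of 28 DIP and dpr genes, 1 was lower in PEN1 (camera adjusted p = 0.0809). With edgeR, 16 of 6249 genes were called, 5 higher and 11 lower in PEN1. DESeq2 called 58, 27 higher and 31 lower. The count was 87 without the filter on low counts, 37 with all wells, 7 with wells of at least 1000 genes, 15 with reporter wells alone, 7 with the control positions kept, 8 without plates P394 to P396, 10 without plate P387, 6 without plate P388, 9 without plate P391 and 10 without plate P395.

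The wells were also counted by marker, as the percentage per plate with at least 10 counts. Reporter wells made up 63.7 ± 12.1% in PEN1 and 29.3 ± 7.54% in PEN2 (two-sided exact permutation p = 0.00216, the smallest the 462 splits of the plates can give). ChAT was found in 67.4 ± 4.56% of PEN1 wells and 54.4 ± 3.67% of PEN2 wells (exact p = 0.00216), Dh44 in 65.4 ± 11.01% and 31.0 ± 6.56% (exact p = 0.00433), br in 2.99 ± 1.90% and 24.7 ± 9.77% (exact p = 0.00216), and Optix in 33.9 ± 8.44% and 48.4 ± 4.53% (exact p = 0.00866). With at least 1 count as the rule, ChAT was found in 85.6 ± 7.00% and 74.8 ± 6.26% of the wells (exact p = 0.0152), and the Optix difference was lost (50.2 ± 10.8% against 59.1 ± 5.73%, exact p = 0.132). By that rule, in wells thinned to 10000 counts, these differences kept their direction, with ChAT in 82.9 ± 3.98% and 66.3 ± 5.13% (exact p = 0.00216) and Optix in 44.0 ± 10.5% and 57.6 ± 7.02% (exact p = 0.0238). The thinning left out 44 PEN1 and 39 PEN2 wells as too shallow. FMRFa (43.1 ± 12.4% against 30.9 ± 8.92%, exact p = 0.108) and Gad1 (2.10 ± 1.45% against 4.57 ± 4.16%, exact p = 0.264) did not pass. Genes for acetylcholine synthesis or transport alone marked most wells that held a transmitter gene. Of the PEN1 wells, 278 held acetylcholine genes, 8 GABA genes and 2 glutamate genes, and of the PEN2 wells 217, 18 and 2.

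**Figure D4:**
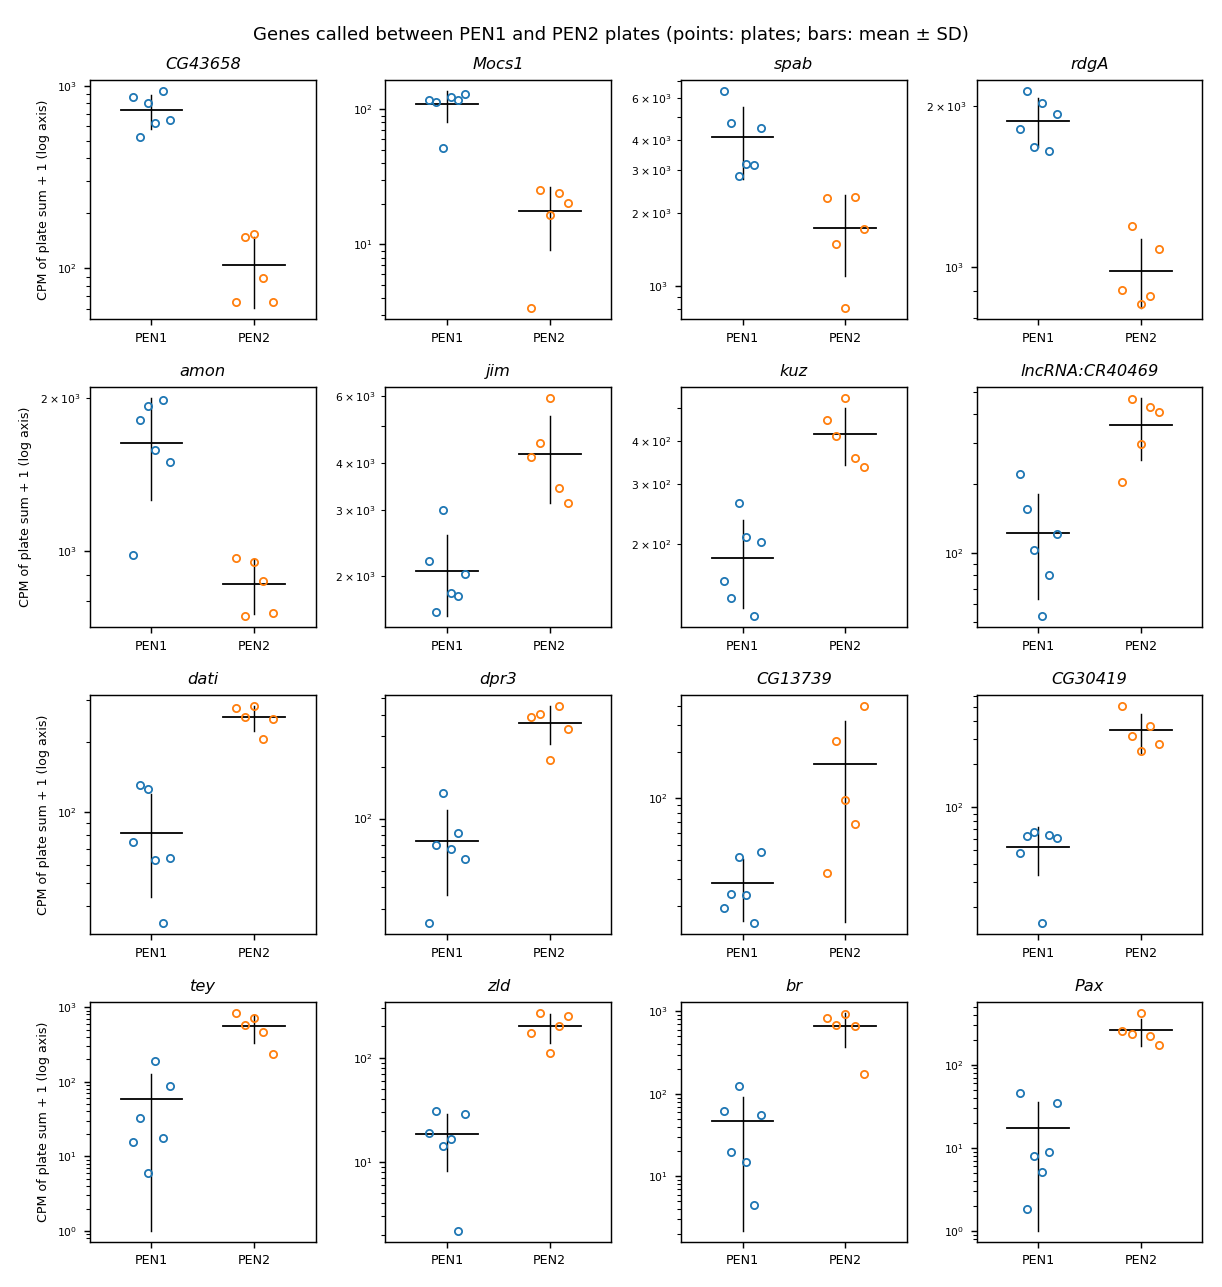
The 16 genes called between PEN1 and PEN2, with CPM of the plate sum + 1 on a log axis, 1 point per plate and bars of the mean ± SD. CG43658 averaged 735 CPM on the 6 PEN1 plates and 103 on the 5 PEN2 plates.

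Bulk and low-cell PEN2 libraries share the driver line but no library, so their fold changes over brain RNA were compared across 5388 genes. The Pearson correlation was 0.472 and the Spearman correlation 0.346, where genes are not independent of each other. Higher in both were 75 genes, against 9.7 by chance from the sizes of the gene sets. This fell to 1 without WB replicate 1, 2 without WB replicate 2, 31 without bulk PEN2 replicate 2 and 11 without scaling. Of 168 and 594 lower genes, 108 were shared, against 18.5 by chance, and 12 genes were called in opposite directions. The shared lower genes were 7 without either WB replicate and 265 without scaling. ITP and Rh2 were lower than brain RNA in both.

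The authors' own tables were compared with the calls made here. The fold changes correlated across genes at 0.895 for D7, 0.884 for EPG, 0.913 for PEG and 0.917 for PEN2 in bulk, and at 0.999 for low-cell R4d and PEN2. The authors' tables held 26 higher and 783 lower genes for D7, of which 25 and 346 were also called here, and 15 and 528 for EPG, of which 15 and 245 were. For bulk PEN2 they held 1 and 10, of which 1 and 5 were called here, and for PEG none, with a smallest FDR of 0.115. For R4d they held 1184 higher and 2185 lower genes, 993 and 1345 of them among the genes tested here, and shared 597 of the 598 higher and 915 of the 919 lower calls made here. For low-cell PEN2 they held 400 and 1853, 354 and 474 of them among the tested genes, of which 346 and 471 were called here. Lmx1a in D7 was 4.7 log2 higher in the authors' table and 5.41 here. No gene was called in opposite directions.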

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

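The tests on PEG replicate 1, VGlut and Gad1 below were chosen only after these results were seen, and the splits of the libraries were planned before. Values were set apart when an outlier test placed 1 library outside the rest of its group, when a label was not used in the comparisons, or when a measure of the libraries stood out. Of 90 groups of values tested for an outlier, 13 held one, where about 1 in 20, or 4.5, would by chance. That rate holds for normally distributed values. Some flags were 1 library above others at or near 0, such as ChT in R4d (5.88 CPM against 0). The 13 are therefore not shown to exceed chance.

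PEG replicate 1 carried more glial and mitochondrial transcripts than the other sorted libraries. RNA of the whole brain was excluded only as the sole source of the glial transcripts. In replicate 1, 15 markers of other brain cells stood at a median of 12.3% of the brain level, with an upper quartile of 39.8%, and glia genes at 349.9%. A share of brain RNA in the library is not excluded by this. Log2 values of replicate 1 correlated at 0.804 and 0.808 with the WB libraries and at 0.733 with PEG replicate 2. Lying nearer to WB than to the own replicate was not particular to this library. PEG replicate 2 correlated at 0.769 with WB, and the PEN2 libraries at 0.717 to 0.755 with WB and 0.707 with each other. The highest correlation of another sorted library with WB was 0.775. The rRNA of PEG replicate 1 made up 41.9% of the FPKM, against 38.0% and 40.8% in WB. A few transcripts taking most of the library were also excluded, because glia genes differed between the PEG replicates by 4.25 log2 more than pan-neuronal genes. Glial cells or their RNA in the library stay open: 7 of 9 glia genes lay above every sorted library of the other types (4 of 9 in replicate 2), but this restates the pattern and does not test its source.

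VGlut stood at 41.2 and 27.3 FPKM in the EPG libraries of line SS00131 and at 0.17 and 0.03 in those of line SS00096. D7 cells or their RNA in these libraries are unlikely as the only source, because 9 other D7 markers stood at a median of 0.0374% of their D7 level and VGlut at 8.45%. The criterion, a median below 0.1 times the VGlut percent, was set after the values were seen, since the first one, on the upper quartile of 6.42%, was undecided. Of the 9 markers, Dh31 (22.5%), ccb (13.6%) and CG4328 (6.42%) were exceptions. RNA of the whole brain is unlikely as the only source by the same criterion, with a median of 0.154% over 15 markers against 33.0% for VGlut. The upper quartile of these markers was 12.1% and the highest 108.7%, so a share of brain RNA is not excluded. A difference between the driver lines is a candidate not tested here.

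Gad1 stood at 239 FPKM in bulk PEN2 replicate 1 and at 4.48 in replicate 2. Gad1 made by the PEN2 cells themselves is unlikely, because 11 of 14 low-cell PEN2 libraries held no Gad1 count. GABAergic cells collected with the PEN2 cells could be the source: of 18 PEN2 wells with Gad1, 1 also held ChAT, against 196 of 344 without Gad1 (two-sided Fisher exact p = 1.06e-05). This p-value treats the wells of 5 plates as independent, although the share of wells with Gad1 ranged from 1.37% to 10.1% per plate. VGAT, however, rose by only 11.5 FPKM where 74.4 would be needed at the brain ratio. With this condition, which was added after the values were seen, the test was undecided.

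The number of genes called could be a result of chance, which was tested by drawing 100 splits of the same libraries. In each of 6 comparisons 1 split of the 100, the real one, called as many genes. This is the lowest rank that 100 splits can give, so a chance placing of these libraries is unlikely for them but not excluded. The comparisons with WB and those of PEG and PEN2 with the other sorted types were not split. The low-cell splits moved libraries that belong to 1 or 2 sample entries per group, so they do not speak to other samples. The highest count of another split was 73 for D7 and 220 for EPG against the other sorted types, 1 for PEN2 and 1 for R4d against CB, 221 for PEN2 against R4d and 2 for PEN1 against PEN2. Why other splits reached 220 and 221 calls was not tested.

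Among measures of the libraries, EPG SS00096 replicate 1 held 3.07% mitochondrial transcripts (2.06% to 2.19% in the other EPG libraries), and R4d library 5 held 10000.5 CPM of the reporter (6214 to 7217 in the others). Among the bulk libraries, ChAT was at 5.84 FPKM in D7 SS02238 replicate 1 (0.02 to 0.45) and at 73.8 in EPG SS00096 replicate 1 (40.7 to 42.5). Gad1 was at 8.72 FPKM in D7 SS02238 replicate 2 (0 to 0.05), Gat at 7.23 in EPG SS00096 replicate 1 (0.05 to 1.23) and VGAT at 32.4 in EPG SS00131 replicate 1 (11.3 to 14.6). Among the low-cell libraries, ChT was at 5.88 CPM in R4d library 3 (0 in the others), VAChT at 8.29 in R4d library 4 (0 to 0.97) and elav at 411 in CB library 7 (213 to 307). On the plates, Gat was at 46.1 CPM on PEN2 plate P390 (0.7 to 0.73), VGlut at 80.6 on PEN1 plate P392 (0.36 to 9.25) and VGlut at 19.4 on PEN2 plate P387 (0.36 to 1.1). The transgenes were not part of the comparisons: nls-tdTomato was at no less than 193 FPKM in a sorted library (7.06 to 7.13 in WB) and myr-GFP-p10 at no less than 25.6 (3.71 to 4.99). Wells E12 and F12 held up to 83405 counts on plates P394 to P396 and 144 to 8610 on the others.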

How the results depend on the processing

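Library weights, pseudocounts, the ceiling of 10000 counts, reporter wells alone, the control positions kept, plates P394 to P396 left out and all settings of the concordance were added after the data were seen. The other alternatives of the comparisons and gene lists were planned before. Of 263 alternative values of 31 results, 197 stayed within 1.5 times or 1 SD and 66 moved. The cause was not tested for any of them. Against WB, in the order D7, EPG, PEG and PEN2, limma called 947, 886, 574 and 740 genes. These became 1859, 1612, 1006 and 1459 as deposited without scaling, 3740, 3699, 3143 and 3420 without the filter, and 1691, 1714, 1581 and 2588 in a fit of only the groups compared. Library weights gave 2236 for D7 and 2096 for EPG. Without WB replicate 1 they were 47, 28, 14 and 17, and without WB replicate 2 they were 50, 30, 13 and 21. Over all libraries left out in turn the ranges were 47 to 919, 28 to 812, 13 to 793 and 17 to 899. With the replicate block, in which equal replicate numbers were treated as paired, the counts were 911, 856, 542 and 717. Against the other sorted types they were 411, 241, 171 and 189. Across 21 pairs of 7 sets of libraries (6 lines and WB), residuals of equal replicate numbers correlated at -0.13 to 0.08.

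Against the other sorted types, the leave-one-out ranges were 330 to 661 for D7, 160 to 507 for EPG, 160 to 497 for PEG and 171 to 496 for PEN2. EPG had 372 without PEN2 replicate 1, 160 without SS00131 replicate 1 and 507 without PEG replicate 2. PEG had 75 with library weights and 497 without PEG replicate 2. PEN2 had 3.9e+02 (346 higher and 46 lower) with upper-quartile scaling, 144 as deposited, 153 in a fit of only the groups compared, 61 with library weights, 454 without PEN2 replicate 1 and 496 without PEG replicate 2. In the low-cell data edgeR called 2377 genes for PEN2 against CB, 2850 for R4d against CB and 2226 for PEN2 against R4d without the filter, and 2493 for R4d against CB in a fit of only the groups compared. On the plates there were 58 calls with DESeq2, 87 without the filter, 37 with all wells, 7 with wells of at least 1000 genes, 7 with the control positions kept and 8 without plates P394 to P396. Leaving out single plates gave 6 to 20, with 10 without P387, 6 without P388, 9 without P391 and 10 without P395.

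With an estimated correlation, the gene lists called fell from 16 to 10 in D7 against WB, 12 to 6 in EPG, 12 to 7 in PEG and 15 to 8 in PEN2. Against the other types they fell from 9 to 3 in D7, 6 to 0 in EPG, 6 to 0 in PEG and 8 to 0 in PEN2, and from 1 to 0 on the plates. In the low-cell data they fell from 16 to 12 in PEN2 against CB, 16 to 14 in R4d against CB and 10 to 8 in PEN2 against R4d. The concordance of bulk and low-cell PEN2 moved from 0.472 to 0.443 with a bulk pseudocount of 5, 0.389 without the low-cell filter, 0.493 with only the low-cell groups compared, 0.455 with PEN2 libraries 1 to 8, 0.39 without bulk replicate 1 and 0.398 without bulk replicate 2, the leave-one-out range being 0.39 to 0.465. The correlation with the authors' PEG table moved from 0.913 to 0.88 without the filter, 0.945 with a pseudocount of 0.1 and 0.881 as deposited, and that for PEN2 from 0.917 to 0.868 as deposited. Of 18224 values of named genes 16820 stayed, 1046 were weaker, 354 were stronger and 4 changed sign. These were Syt4 in D7 against WB (-0.12) and Sh in EPG against WB (-1.05) as deposited, mt:lrRNA in PEG against WB without PEG replicate 1 (-2.18, and 2.6 without replicate 2), and AstC in PEN2 against R4d with PEN2 libraries 1 to 8 (-3.61). The planned DESeq2 fit of the bulk data was not run because the values are not counts.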

Other observations

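The single wells and RpL3 described here were looked up only after the results were seen. A few wells supplied most of the counts of a gene on the plates. Of the Vm34Ca counts of all PEN2 wells, 85.3% lay in well D01 of plate P390, as did 99.8% of the dhd counts and 80.2% of the Yp1 counts, all 3 being genes of the ovary or the fat body. Of the SIFa counts of all PEN1 wells, 97.6% lay in well D03 of plate P392, which held 897320 counts in all, and 97.3% of the CG12239 counts lay there as well. Gs2, of glia, had 56.6% and 35.0% of its PEN2 counts in wells D11 and E11 of plate P390 and 51.3% of its PEN1 counts in well G09 of plate P391.

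The PEN2 wells with Gad1 also held other genes found in PEN2 libraries, and the reporter, less often, which was counted but not tested. Of 18 such wells, 1 held Optix, 0 held Dh44, 0 held FMRFa and 3 held the reporter, against 175, 112, 113 and 103 of the 344 wells without Gad1. RpL3 was at 0.944 ± 0.239 FPKM in bulk PEN2 and at 1326 ± 544 CPM in low-cell PEN2, where CB held 911 ± 208 CPM.

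The low share of reporter wells among the PEN2 plates and the Gad1 wells raise the hypothesis that part of the PEN2 wells hold other neurons. A weak reporter could also give a low share, since the bulk PEN2 libraries held 296 and 193 FPKM of it and the other sorted libraries 431 to 1525. With reporter wells alone, 15 genes were called between PEN1 and PEN2 in place of 16, and with wells of at least 1000 genes, a filter on depth and not on cell type, 7 were. A test would be to score Optix, Dh44 and the reporter in the same brains by in situ hybridization. For PEG replicate 1, the source of the glial transcripts is open, and glial cells or their RNA in the library could be tested by sorting PEG cells again and counting glial nuclei in the sorted sample. For VGlut in EPG line SS00131, where 9 D7 markers stood at a median of 0.0374% of their D7 level, with Dh31 (22.5%), ccb (13.6%) and CG4328 (6.42%) as exceptions, an in situ hybridization of VGlut in both EPG lines would show whether the lines differ.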
